A study of Mus musculus with 8 samples.

How the data were processed

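Total RNA of mouse embryonic stem cells was measured on Affymetrix GeneChip expression arrays with biotin-labelled cRNA, 1 array per sample. Per the labels, 3 samples were treated for 60 h with DMSO, 2 for 60 h with 64 μM of a small-molecule MYC inhibitor, and 3 for 60 h with the inhibitor and then 48 h without it. The deposited values are log2 expression values, 1 per probe set and array. The submitters' processing notes name RMA, oligo 1.32.0 and limma 3.2.15. That the scale is log2 was read from the values, which run from 1.69 to 13.76 with near-equal quartiles on all arrays. RMA corrects the background, equalises the distribution of values between arrays by quantile normalization and summarises the probes of a probe set. The values are therefore relative within an array, and a change of RNA amount per cell shared by most genes is not visible. No detection calls were used here. Bacterial Trpn control probe sets lay between 2.15 and 2.95 on the 8 arrays, and fold changes of genes near this level are compressed.

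The deposited values cover 45101 probe sets. Of these, 34945 have 1 gene symbol in the platform annotation, 932 have several, 9160 are not named here and 64 are controls. Gene numbers of 34741 probe sets were found in a RefSeq list of genes of the assembly GRCm38.p6, which changed 0 symbols, and no coordinates were used. Only probe sets with 1 gene were tested, and of the 9010 genes with more than 1 probe set the one with the highest mean over all 8 arrays was kept, which left 18193 genes. No filter on level was applied. When every probe set was tested, opposite calls were found in 339 of 8565 genes with a called probe set between inhibitor-treated and DMSO arrays, in 12 of 1865 between released and DMSO arrays, and in 277 of 8451 between released and inhibitor-treated arrays.

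Comparisons were made in R 4.3.3 with limma 3.58.1 (lmFit and eBayes), with 1 mean per group and all 8 arrays in 1 fit, which left 5 residual degrees of freedom. The prior had 4.55 degrees of freedom and a variance of 0.00789. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the 18193 genes of each comparison, with a threshold of 0.05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for reading tables and drawing.

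A total of 29 gene lists was fixed before the data were examined, as were the comparisons and the rule for naming genes. Of these, 24 cover pathways and gene groups and 5 cover markers of fibroblasts and feeder cells, endoderm, trophectoderm, mesoderm and neural cells. Krt18 stands both in the formative and primed list and in the trophectoderm list. Members without a probe set of 1 gene, such as Gapdh and Bax, were not analysed here. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 29 lists, and again with the correlation estimated per list and with fry. Named genes were, per comparison, the 12 largest rises and the 12 largest falls among genes that passed the threshold and whose arrays did not overlap between groups, leaving out symbols of unnamed gene models. To these came up to 4 members per list with the smallest p, and always Myc, Mycn, Max, Pou5f1, Sox2, Nanog, Klf4, Esrrb and Zfp42.

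The procedure was tested on simulated data for 18193 genes. Of genes changed by a log2 value of 0.5, it recovered 90% for inhibitor-treated against DMSO arrays, 96% for released against DMSO and 92% for released against inhibitor-treated arrays, and of genes changed by 1 or 2 it recovered 100% in each. The false share among calls was 3.62%, 3.9% and 6.58%. Alternatives were the mean of all probe sets, every probe set, a filter at the 30th percentile of level, median centring, repeated quantile normalization, a variance trend with robust fitting, array weights, only the arrays of the groups compared, stricter thresholds, the replicate number as a block, and leaving out each array. Dividing the DMSO arrays between the comparisons was added after the data were seen.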

Results

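Mouse embryonic stem cells (ESCs), the cultured counterpart of the pluripotent cells of the early embryo, were grown without feeder cells or serum in 2i medium. This medium holds leukaemia inhibitory factor with PD0325901 at 1 μM, a MEK inhibitor, and CHIR99021 at 3 μM, a GSK3 inhibitor. RNA from 8 samples was hybridised to 8 GeneChip arrays. There were 3 arrays of cells treated for 60 h with DMSO, the solvent of the compound, and 2 arrays of cells treated for 60 h with 64 μM of a small-molecule MYC inhibitor that disrupts the pairing of MYC with its partner MAX. In the last group of 3 arrays, called released cells, the inhibitor was withdrawn after 60 h and the cells were cultured for 48 h more in 2i medium. The comparisons asked which transcripts changed with the inhibitor, which changed on its withdrawal, and which still differed from DMSO after withdrawal. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these arrays, which may be technical. Array data have no read depth, and the number of arrays limits the precision. The median moderated standard error of a log2 change was 0.0828 for the inhibitor-treated against the DMSO arrays and 0.0741 for the released against the DMSO arrays.

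The 3 groups were separated on the arrays. Over 18193 genes, Pearson correlations between arrays of 1 group lay between 0.9977 and 0.9982, those between DMSO and released arrays between 0.9954 and 0.9962, and those between inhibitor-treated and DMSO arrays between 0.9803 and 0.9808. These correlations run across genes, which are not independent replicates. The first principal component held 74.7% of the variance and set the 2 inhibitor-treated arrays apart from the other 6. The second held 11.4% and separated DMSO from released arrays. Differences between the 3′ and 5′ control probe sets of Gapdh, a measure of RNA integrity, were -0.124, -0.13 and -0.108 (log2) on the DMSO arrays, -0.148 and -0.216 on the inhibitor-treated arrays, and -0.132, -0.117 and -0.133 on the released arrays. For Actb they lay between 0.248 and 0.288 on all 8 arrays.

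After 60 h with the inhibitor, most measured genes of DNA replication, mitosis, nucleotide synthesis and ribosome biogenesis were lower than in DMSO, and most of those of the integrated stress response, lysosome and oxidative defence lists were higher, while Pou5f1, Sox2 and Nanog did not pass the test. With an estimated correlation the calls of these 7 lists did not hold (camera adjusted p from 0.115 to 0.216). Each kept its call under 16 of 17 alternatives, most of which used the preset correlation. Of 18193 genes, 7557 passed an adjusted p of 0.05 in limma, of which 3497 rose and 4060 fell. The balance turned without inhibitor-treated replicate 2 (2986 higher and 2945 lower) and at an adjusted p under 0.01 (2770 and 2749), and with median centring it was 3169 and 5138. Most changes were small. The median absolute log2 change among them was 0.452, and 880 genes changed at least 2-fold, 580 upward and 300 downward. The values of the 2 groups did not overlap for 60.5% of genes, against 20% by chance with 2 and 3 arrays. Values of single genes are given as log2 changes ± moderated standard error, here from 2 inhibitor-treated and 3 DMSO arrays. They come from the kept probe set, and other probe sets of some genes changed less, more or with the other sign. Over all probe sets, Eif4e ran from -1.02 to 0.04 and Hmgcs1 from 0.60 to 1.48.

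The largest rise was that of Gpnmb, a transmembrane glycoprotein of lysosomes and melanosomes, which was 72.9-fold higher (6.19 ± 0.11; limma adjusted p = 2e-09). Its mean level was 5.19 ± 0.15 (SD, n = 3) with DMSO and 11.37 ± 0.03 (SD, n = 2) with the inhibitor. The keratins of simple epithelia Krt18 (5.0 ± 0.15) and Krt19 (4.94 ± 0.15) rose 31.9-fold and 30.7-fold. Ptgs2, the inducible prostaglandin synthase, rose 22.6-fold (4.50 ± 0.087) and the small heat shock protein gene Cryab 19.3-fold (4.27 ± 0.13). Other large rises were those of the calcium-binding protein genes S100a6 (4.26 ± 0.11) and Anxa3 (3.99 ± 0.11). The transcription factor genes Cebpb (3.84 ± 0.10) and Jun (3.83 ± 0.18), the amyloid precursor gene App (3.67 ± 0.096) and the mitochondrial thioesterase gene Acot2 (3.66 ± 0.085) rose too. Krt19, Ptgs2 and Cryab lay between 2.70 and 3.64 in DMSO, close to the 2.15 to 2.95 of bacterial Trpn control probe sets over all arrays, so their fold changes are compressed and not exact. The lowest changes among all probe sets of a gene were 2.86 for Gpnmb, 2.51 for Ptgs2, 1.58 for Jun, -0.04 for Cryab and -0.25 for App.

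The largest fall was that of Lefty2, which was 17.9-fold lower (-4.16 ± 0.069; limma adjusted p = 2e-09). Lefty1 fell as well (-2.77 ± 0.097); both encode secreted antagonists of Nodal. The homeobox genes Nkx1-2 (-3.88 ± 0.13) and Gbx2 (-2.56 ± 0.11) fell, as did Lin28a (-2.83 ± 0.094), whose RNA-binding product blocks let-7 maturation. Among cell cycle genes, Ccnd1, which encodes cyclin D1, fell 6.53-fold (-2.71 ± 0.074) and Pclaf, a PCNA-binding factor, fell 7.76-fold (-2.96 ± 0.072). The cytochrome oxidase subunit gene Cox7a1 (-3.12 ± 0.15), the LIM-domain gene Crip1 (-2.77 ± 0.075), the myogenic fusion gene Mymx (-2.48 ± 0.067) and Id3, an inhibitor of basic helix-loop-helix factors (-2.43 ± 0.081), completed the largest falls together with Jade2 (-2.39 ± 0.18). The smallest falls among all probe sets of a gene were -1.01 for Lin28a, -0.38 for Nkx1-2, -0.26 for Jade2 and -0.02 for Pclaf.

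The transcripts of MYC itself and its closest partners did not pass the test. Myc differed by -0.17 ± 0.12 (limma adjusted p = 0.316), Mycn by -0.07 ± 0.063 (0.389) and Max by -0.10 ± 0.074 (0.319), none past the threshold. The compound acts on the protein pair, so these levels do not check the labels. In the MYC network list, of 13 measured members 1 rose and 5 fell (1 and 5 adjusted over the list alone). Mycl (-1.04 ± 0.082) and the MAX-binding repressor gene Mxd3 (-1.05 ± 0.11) fell and Mga (0.30 ± 0.068) rose, a call that ended with the mean of its probe sets (limma adjusted p = 0.229). The list was not called (camera adjusted p = 0.407).

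Proliferation lists fell almost as a whole. In G2 and mitosis, of 29 measured members 0 rose and 29 fell (0 and 29 adjusted over the list alone), with a median of -1.02. Ccnb2, encoding cyclin B2, fell 3.48-fold (-1.80 ± 0.060), and the anaphase ubiquitin ligase partner Ube2c (-1.75 ± 0.065), the mitotic kinesin Kif20a (-1.49 ± 0.067) and the centromeric histone Cenpa (-1.40 ± 0.069) fell similarly. In DNA replication, of 34 measured members 0 rose and 31 fell (0 and 31 adjusted over the list alone), with a median of -0.71. The origin licensing factor Cdc6 fell 4.24-fold (-2.08 ± 0.079), Ccne1, encoding cyclin E1, fell 3.56-fold (-1.83 ± 0.069), and Gins1 (-1.58 ± 0.061) and Rpa2 (-1.08 ± 0.063) fell too. In nucleotide biosynthesis, of 26 measured members 1 rose and 23 fell (2 and 23 adjusted over the list alone), with a median of -0.44; thymidine kinase Tk1 (-1.82 ± 0.069) and the ribonucleotide reductase subunits Rrm2 (-1.57 ± 0.072) and Rrm1 (-1.18 ± 0.064) fell most clearly. G2 and mitosis was called lower (camera adjusted p = 8.82e-18, and adjusted p = 0.115 with an estimated correlation). DNA replication was called lower (camera adjusted p = 2.63e-14, and adjusted p = 0.115 with an estimated correlation), as was nucleotide biosynthesis (camera adjusted p = 1.17e-07, and adjusted p = 0.115 with an estimated correlation). In all, camera called 13 of the 29 lists with the inhibitor, 7 upward and 6 downward. With an estimated correlation, camera called 0 of the 29 fixed lists in each of the 3 comparisons. At an unadjusted p under 0.05 it then called 7 here, 2 between released and DMSO arrays and 5 between released and inhibitor-treated arrays, and fry, which tests a list without setting it against other genes, called 27, 6 and 25.

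The list of cell cycle inhibitors and p53 targets went mostly the other way: of 25 measured members 14 rose and 5 fell (14 and 5 adjusted over the list alone). Plk2 (2.41 ± 0.076), Gadd45a (2.15 ± 0.089) and Mdm2 (0.89 ± 0.067), all known p53 targets, rose, and Pmaip1, which encodes the pro-apoptotic protein NOXA, fell (-0.87 ± 0.073). Of 2 probe sets of Plk2, 1 passed. The list was called higher (camera adjusted p = 0.00985, and adjusted p = 0.532 with an estimated correlation).

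Ribosome biogenesis and protein synthesis genes divided. In ribosome biogenesis, of 46 measured members 1 rose and 30 fell (1 and 33 adjusted over the list alone), with a median of -0.35 and a call downward (camera adjusted p = 1.12e-07, and adjusted p = 0.216 with an estimated correlation). The RNA polymerase I subunit gene Polr1e (-0.99 ± 0.092), Lyar (-0.93 ± 0.072) and the small nucleolar ribonucleoprotein genes Gar1 (-0.77 ± 0.067) and Nhp2 (-0.66 ± 0.057) fell. The cytosolic ribosomal protein genes showed few calls: of 34 measured members 2 rose and 4 fell (1 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.679). Among initiation and elongation factors, of 23 measured members 2 rose and 10 fell (3 and 10 adjusted over the list alone), without a call (camera adjusted p = 0.39). Eif4e, the cap-binding factor, fell (-0.50 ± 0.075) and Eif3c rose (0.47 ± 0.068). Among aminoacyl-tRNA synthetases, of 19 measured members 9 rose and 4 fell (9 and 5 adjusted over the list alone). Wars rose 1.96-fold (0.97 ± 0.061), with Eprs (0.63 ± 0.061), Sars (0.60 ± 0.068) and Aars (0.49 ± 0.067), and the list was called higher (camera adjusted p = 0.035, and adjusted p = 0.589 with an estimated correlation). This call ended under 5 of 17 alternatives, among them without low-level genes (0.0953), without DMSO replicate 1 (0.0535) and without inhibitor-treated replicate 1 (0.0866).

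Pluripotency genes did not move in 1 direction. Pou5f1 differed by -0.04 ± 0.072 (limma adjusted p = 0.666), Sox2 by 0.12 ± 0.073 (0.246) and Nanog by -0.10 ± 0.058 (0.219); none passed the threshold. With a variance trend and robust fitting Nanog passed (limma adjusted p = 0.0407). The naive factors Klf4 (0.46 ± 0.076) and Zfp42 (0.69 ± 0.073) rose. Esrrb passed narrowly (0.20 ± 0.059; limma adjusted p = 0.0195), and its call ended under 6 of 17 alternatives, among them with the mean of its probe sets (0.999), with median centring (0.0502), and without DMSO replicate 3 (0.0517), inhibitor-treated replicate 1 (0.112) or replicate 2 (0.052). In contrast, Utf1 (-1.79 ± 0.061) and Tcl1 (-1.11 ± 0.066) fell, besides Lin28a and Gbx2. In the list of naive and general pluripotency factors, of 30 measured members 9 rose and 14 fell (11 and 14 adjusted over the list alone), and it was not called (camera adjusted p = 0.44). In the list of formative and primed markers, of 18 measured members 3 rose and 9 fell (3 and 9 adjusted over the list alone), and it was not called (camera adjusted p = 0.154). Its falling members with the smallest p were Lefty2, Lefty1 and the DNA methyltransferase gene Dnmt3b (-0.67 ± 0.063), and Krt18 was its largest rise.

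**Figure D1:**
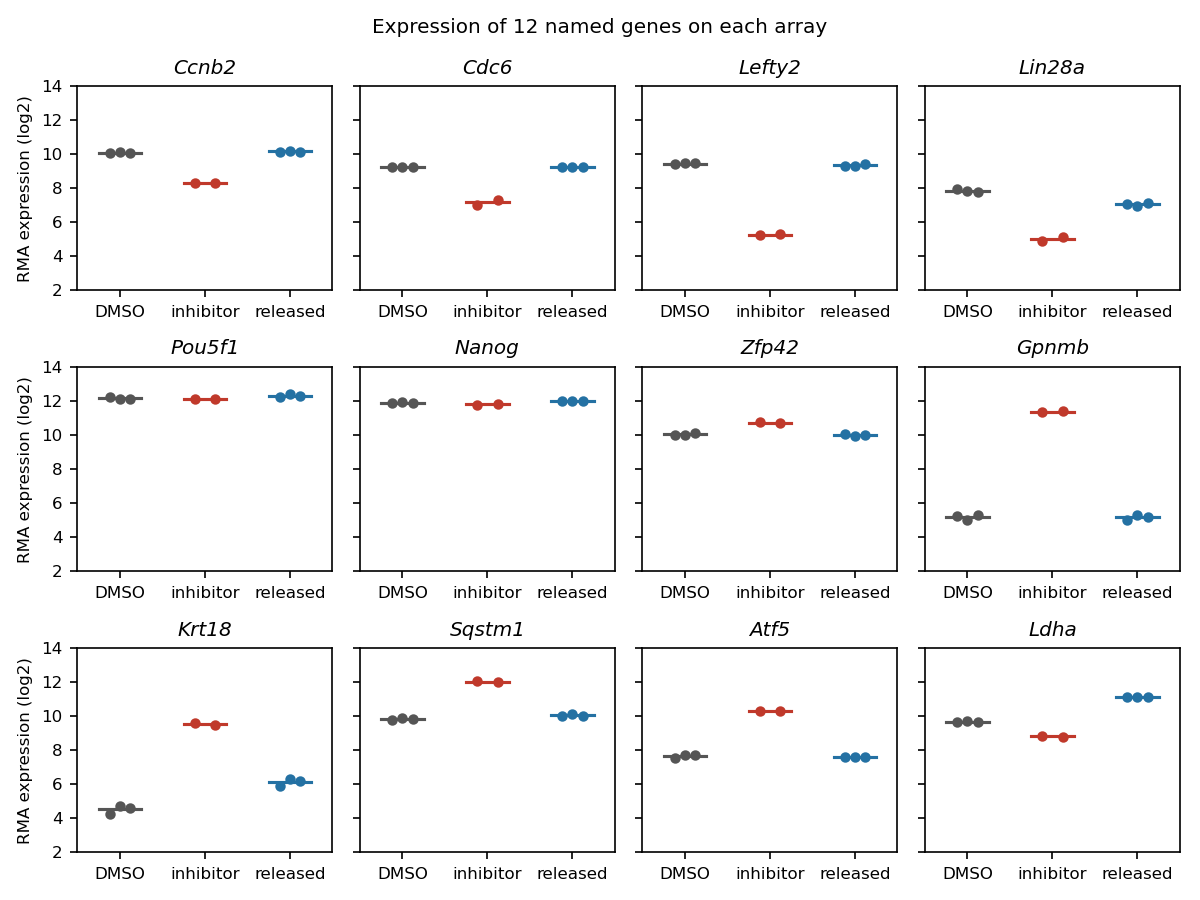
Expression of 12 named genes on each of the 8 arrays (y axis, RMA value on the log2 scale; x axis, DMSO, inhibitor-treated and released groups; points are arrays and bars group means). Ccnb2, Cdc6, Lefty2 and Lin28a are lower and Gpnmb, Krt18, Sqstm1 and Atf5 higher on both inhibitor-treated arrays, Pou5f1 and Nanog stay near 12 in all groups, and Ldha is highest in the released group.

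The integrated stress response, lysosome and oxidative defence lists were called higher, and that of heat shock and the unfolded protein response was not called (camera adjusted p = 0.34). In the amino acid and integrated stress response list, of 25 measured members 21 rose and 0 fell (21 and 0 adjusted over the list alone), with a median of 0.81 and a call upward (camera adjusted p = 5.78e-14, and adjusted p = 0.19 with an estimated correlation). Besides Cebpb, the transcription factor gene Atf5 (2.63 ± 0.071), the pseudokinase gene Trib3 (1.82 ± 0.075) and Ddit4, whose product restrains mTORC1 (1.89 ± 0.080), rose. In the lysosome and autophagy list, of 33 measured members 24 rose and 2 fell (24 and 2 adjusted over the list alone), with a median of 0.77 and a call upward (camera adjusted p = 1.85e-11, and adjusted p = 0.216 with an estimated correlation). The autophagy receptor gene Sqstm1 rose 4.53-fold (2.18 ± 0.067), and the lysosomal genes Psap (1.59 ± 0.070), Gaa (1.55 ± 0.077) and Ctsd (1.52 ± 0.072) rose 3.01-fold, 2.93-fold and 2.87-fold. In the xenobiotic and oxidative stress list, of 21 measured members 16 rose and 4 fell (16 and 4 adjusted over the list alone), with a median of 0.86 and a call upward (camera adjusted p = 3.73e-07, and adjusted p = 0.136 with an estimated correlation). Sulfiredoxin Srxn1 rose 7.57-fold (2.92 ± 0.11), both subunits of glutamate-cysteine ligase rose, Gclm by 1.87 ± 0.061 and Gclc by 1.15 ± 0.065, and thioredoxin reductase Txnrd1 rose by 1.03 ± 0.060.

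In energy metabolism, oxidative phosphorylation genes fell: of 31 measured members 0 rose and 22 fell (0 and 23 adjusted over the list alone), with a median of -0.26. The falls were small, as for the cytochrome oxidase genes Cox7a2 (-0.77 ± 0.074) and Cox6c (-0.66 ± 0.068) and the succinate dehydrogenase gene Sdhd (-0.66 ± 0.066). The list was called lower (camera adjusted p = 6.23e-06, and adjusted p = 0.532 with an estimated correlation). Glycolysis genes were mixed, since of 19 measured members 5 rose and 9 fell (5 and 9 adjusted over the list alone), and the list was not called (camera adjusted p = 0.34). The pyruvate dehydrogenase kinase gene Pdk1 (-1.30 ± 0.072), Tpi1 (-0.92 ± 0.061) and the lactate dehydrogenase genes Ldhb (-0.96 ± 0.073) and Ldha (-0.86 ± 0.062) fell.

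Among signalling lists, of 13 measured members 0 rose and 7 fell (0 and 7 adjusted over the list alone) in that of Wnt targets, which was called lower (camera adjusted p = 0.00294, and adjusted p = 0.19 with an estimated correlation). Besides Ccnd1, its falling genes with the smallest p were Cdx1 (-1.56 ± 0.088), Sp5 (-1.24 ± 0.10) and Notum (-0.70 ± 0.066). The FGF and ERK target list was divided: of 19 measured members 6 rose and 5 fell (6 and 5 adjusted over the list alone), with a median of -0.078 and a mean of 0.22, opposite in sign, and no call (camera adjusted p = 0.543). Fos (1.91 ± 0.077), Phlda1 (2.51 ± 0.12) and Dusp5 (1.37 ± 0.099) rose and Dusp6 fell (-0.99 ± 0.083). Germline genes were more often higher than lower: of 24 measured members 11 rose and 3 fell (12 and 3 adjusted over the list alone), with a call upward (camera adjusted p = 0.00769, and adjusted p = 0.5 with an estimated correlation) that ended without low-level genes (0.0953). Stk31 rose 3.66-fold (1.87 ± 0.13), the RNA-binding protein gene Dazl 2.93-fold (1.55 ± 0.059) and the meiotic axis gene Sycp3 2.51-fold (1.33 ± 0.11), and Dmrt1 rose by 0.80 ± 0.069.

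Of the 5 lists of markers of other cell types, that of trophectoderm was called higher (camera adjusted p = 0.00496, and adjusted p = 0.194 with an estimated correlation). In it, of 16 measured members 8 rose and 2 fell (8 and 2 adjusted over the list alone); the keratins Krt8 (3.24 ± 0.086), Krt18 and Krt19 led it, followed by the transcription factor gene Gata3 (1.28 ± 0.12). Its mean was 0.99 and its median 0.23. Among fibroblast and feeder markers, of 15 measured members 2 rose and 2 fell (2 and 2 adjusted over the list alone), without a call (camera adjusted p = 0.85). Vim fell (-1.04 ± 0.085) and Fn1 rose (0.40 ± 0.078). Among endoderm markers, of 17 measured members 1 rose and 4 fell (1 and 4 adjusted over the list alone), without a call (camera adjusted p = 0.557). Lamb1 fell (-1.02 ± 0.068) and Col4a2 rose (0.80 ± 0.13). Among mesoderm markers, of 14 measured members 1 rose and 3 fell (1 and 3 adjusted over the list alone), without a call (camera adjusted p = 0.882). Eomes rose 4.69-fold (2.23 ± 0.070) and Gsc fell (-1.57 ± 0.076). Among neural markers, of 14 measured members 0 rose and 5 fell (0 and 5 adjusted over the list alone), without a call (camera adjusted p = 0.155). Map2 (-2.13 ± 0.12) and Tubb3 (-1.39 ± 0.079) fell.

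**Figure D2:**
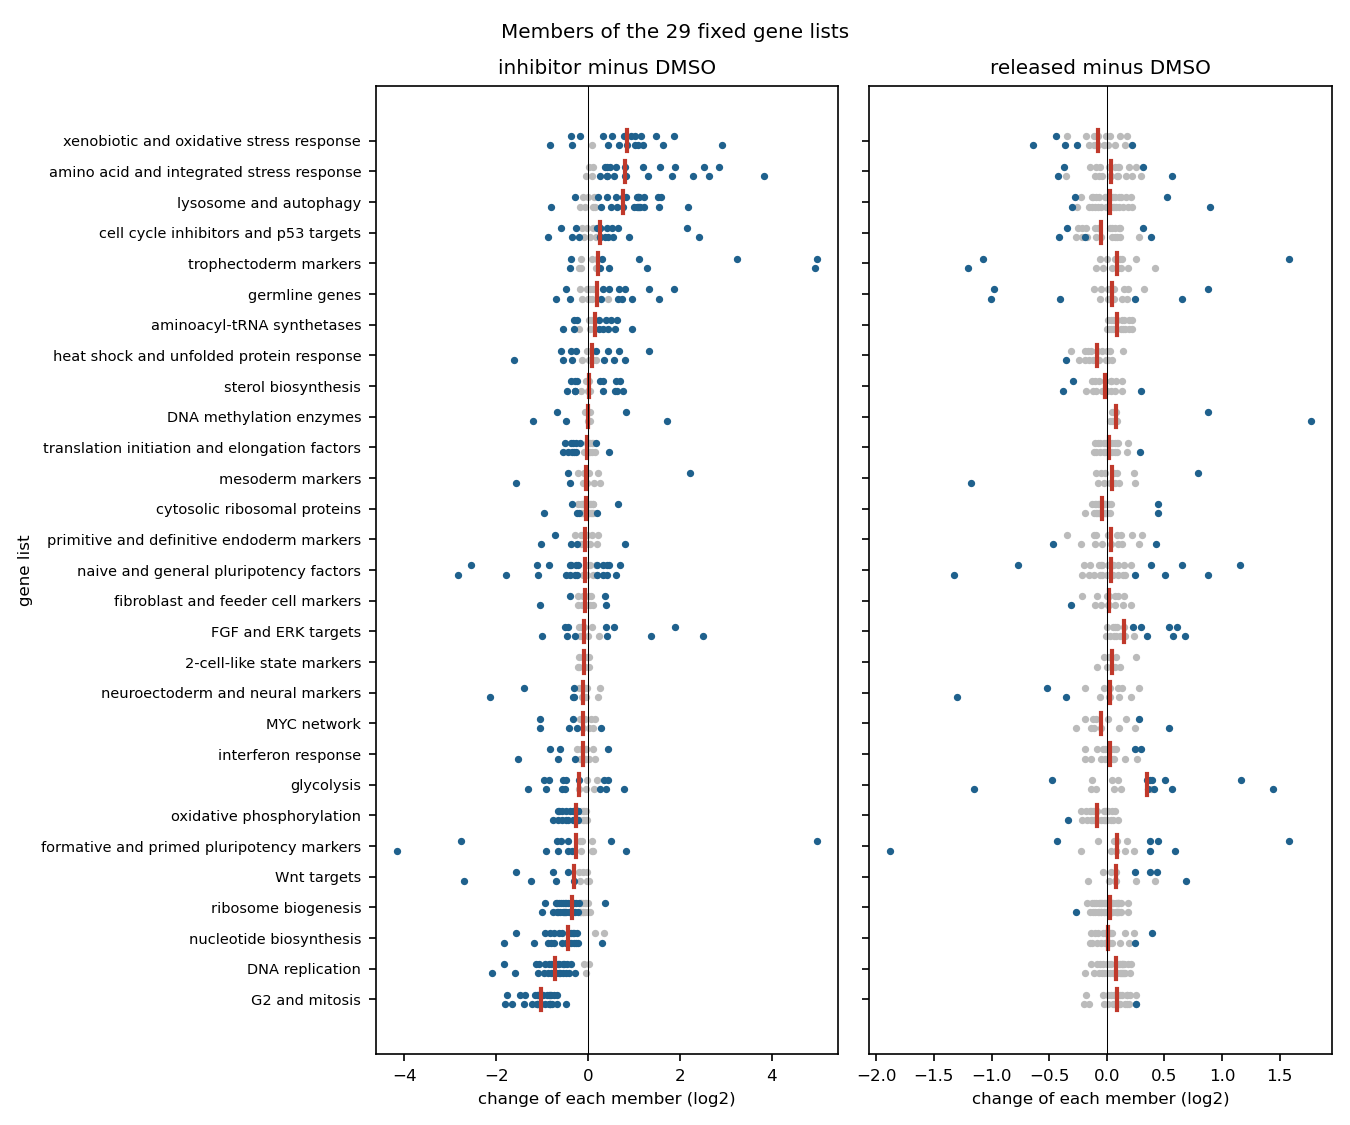
Log2 change of each measured member (x axis) of the 29 fixed gene lists (y axis) in inhibitor-treated against DMSO arrays (left) and released against DMSO arrays (right). Blue points passed an adjusted p of 0.05, grey points did not, and red bars are list medians; G2 and mitosis has the lowest median on the left, -1.02, and glycolysis has the highest on the right, 0.35.

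After withdrawal of the inhibitor, most measured genes of DNA replication, mitosis, nucleotide synthesis and ribosome biogenesis were higher than in inhibitor-treated cells, and most of those of the lysosome, integrated stress response and oxidative defence lists were lower. With an estimated correlation the calls of these lists did not hold (camera adjusted p from 0.101 to 0.202). Each kept its call under 16 of 17 alternatives, most of which used the preset correlation. Nkx1-2 (4.36 ± 0.13), Lefty2 (4.09 ± 0.069), Id3 (3.23 ± 0.081), Cox7a1 (3.22 ± 0.15), Gbx2 (3.21 ± 0.11) and Ccnd1 (2.96 ± 0.074) had the largest rises. Gpnmb fell 73.7-fold (-6.20 ± 0.11), and Krt19 (-4.82 ± 0.15), Ptgs2 (-4.42 ± 0.087), Jun (-4.35 ± 0.18) and the scaffold protein gene Ush1c (-4.21 ± 0.14) followed. When every probe set was tested, Myc (0.71) and Nanog (0.20) passed as higher after release. Zfp42 (-0.73) and both probe sets of Klf4 (-0.57 and -0.38) passed as lower. Mycn, Max, Pou5f1, Sox2 and Esrrb did not pass there. Between 3 released and 2 inhibitor-treated arrays, 7616 of 18193 genes passed in limma, 4122 higher and 3494 lower after release, and 960 changed at least 2-fold, 348 upward and 612 downward. The balance over all genes that passed turned without inhibitor-treated replicate 2 (2990 higher and 3013 lower).

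In the G2 and mitosis list, of 29 measured members 29 rose and 0 fell (29 and 0 adjusted over the list alone) after release (camera adjusted p = 2.25e-18, and adjusted p = 0.101 with an estimated correlation). For DNA replication, of 34 measured members 31 rose and 0 fell (33 and 0 adjusted over the list alone), with camera adjusted p = 2.03e-15, and adjusted p = 0.101 with an estimated correlation. For ribosome biogenesis, of 46 measured members 34 rose and 1 fell (34 and 1 adjusted over the list alone), with camera adjusted p = 2.9e-08, and adjusted p = 0.202 with an estimated correlation. For nucleotide biosynthesis, of 26 measured members 23 rose and 1 fell (23 and 1 adjusted over the list alone), with camera adjusted p = 2.9e-08, and adjusted p = 0.101 with an estimated correlation. Lysosome and autophagy genes went down, since of 33 measured members 2 rose and 25 fell (2 and 25 adjusted over the list alone), with camera adjusted p = 2.24e-11, and adjusted p = 0.202 with an estimated correlation. In the amino acid and integrated stress response, of 25 measured members 1 rose and 20 fell (2 and 20 adjusted over the list alone), with camera adjusted p = 2.24e-11, and adjusted p = 0.202 with an estimated correlation. In the xenobiotic and oxidative stress list, of 21 measured members 3 rose and 16 fell (3 and 16 adjusted over the list alone), with camera adjusted p = 7.07e-08, and adjusted p = 0.101 with an estimated correlation. Among cell cycle inhibitors and p53 targets, of 25 measured members 5 rose and 14 fell (5 and 14 adjusted over the list alone), a call downward (camera adjusted p = 0.00243, and adjusted p = 0.396 with an estimated correlation). Among trophectoderm markers, of 16 measured members 3 rose and 8 fell (5 and 8 adjusted over the list alone), also a call downward (camera adjusted p = 0.0115, and adjusted p = 0.202 with an estimated correlation). Oxidative phosphorylation was called higher, as of 31 measured members 16 rose and 0 fell (17 and 0 adjusted over the list alone), with camera adjusted p = 0.000529, and adjusted p = 0.502 with an estimated correlation. Wnt targets were called higher too, as of 13 measured members 9 rose and 0 fell (9 and 0 adjusted over the list alone), with camera adjusted p = 0.000154, and adjusted p = 0.101 with an estimated correlation.

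Of the 7557 genes that passed in inhibitor-treated cells, 6117 (80.94%) moved in the opposite direction past the threshold on release, and 6428 (85.06%) did not pass against DMSO after release. Of the 10636 genes that had not passed with the inhibitor, 95.8% did not pass against DMSO after release, and of all genes 91.34%. Both counts share arrays with the first comparison. In 100 simulations of released arrays left at the inhibitor-treated mean, at most 1 gene moved back past the threshold, and from 8.664% to 10.54% of the genes that passed with the inhibitor did not pass against DMSO. Among the 880 genes changed at least 2-fold by the inhibitor, 870 moved back past the threshold, and the median difference that remained against DMSO was 2.615% of the initial log2 change (interquartile range -9.533% to 15.39%). In the same direction as with the inhibitor, 164 of them still differed from DMSO, 13 of them by at least 2-fold. Krt18 was among the 13, at 3-fold higher than in DMSO (1.59 ± 0.13; limma adjusted p = 0.000116). With the mean of all probe sets the 164 became 109.

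In released against DMSO cells, 7 of 19 measured FGF and ERK targets and 9 of 19 measured glycolysis genes were higher, 0 and 2 were lower, and the others did not pass. With an estimated correlation the 2 lists had adjusted p = 0.109 and adjusted p = 0.389. Otx2 and Dppa3 were lower. Of 18193 genes, 1576 passed in limma, 847 higher and 729 lower, with 55 changed at least 2-fold. The balance turned with median centring (824 higher and 845 lower) and without released replicate 2 (498 and 502). The values of the 2 groups of 3 did not overlap for 28.6% of genes, against 10% by chance. The released cells had also been 48 h longer in culture, and time in culture and release cannot be told apart in this design. Without released replicate 1 the count was 1008 and without released replicate 2 it was 1000. The genes with the largest rises were Cd3g (2.24 ± 0.091) and Cd3d (1.81 ± 0.085), which encode chains of the T cell receptor complex, and Dnmt3l (1.77 ± 0.080), a cofactor of de novo DNA methylation that had also risen with the inhibitor (1.72 ± 0.089). The growth factor gene Igf2 (1.55 ± 0.14), Bach2 (1.48 ± 0.092), Ldha (1.44 ± 0.056), A2m (1.42 ± 0.11) and Bnip3, a mitophagy receptor gene (1.38 ± 0.072), rose too. The largest falls were those of Otx2, a transcription factor gene of the formative state, which was 3.67-fold lower (-1.88 ± 0.14), Gstm5 (-1.53 ± 0.12), Mt4 (-1.51 ± 0.099) and Dppa3, a maternal factor expressed in naive and germ cells (-1.33 ± 0.065). Map2 (-1.30 ± 0.11), Hesx1 (-1.23 ± 0.080), Krt17 (-1.23 ± 0.11), Krt7 (-1.21 ± 0.18) and Gsc (-1.18 ± 0.068) fell too. Of 4 probe sets of Map2, 1 passed, and the lowest changes among all probe sets were -0.01 for Igf2 and -0.03 for Bach2.

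Between released and DMSO arrays, 11 of the 29 lists were called, 8 upward and 3 downward. In FGF and ERK targets, of 19 measured members 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.15 and a call upward (camera adjusted p = 7.72e-05, and adjusted p = 0.109 with an estimated correlation). The feedback phosphatase gene Dusp6 (0.68 ± 0.074), Spred1 (0.61 ± 0.075) and the ETS factor genes Etv4 (0.57 ± 0.072) and Etv5 (0.35 ± 0.061) rose. Of 8 probe sets of Spred1, 2 passed, and of 2 probe sets of Etv4, 1 passed. In glycolysis, of 19 measured members 9 rose and 2 fell (10 and 2 adjusted over the list alone), with a median of 0.35 and a call upward (camera adjusted p = 0.00101, and adjusted p = 0.389 with an estimated correlation). Besides Ldha, the phosphofructokinase genes Pfkl (1.16 ± 0.073) and Pfkp (0.57 ± 0.064) rose, and Ldhb fell (-1.15 ± 0.065). In Wnt targets, of 13 measured members 4 rose and 0 fell (6 and 1 adjusted over the list alone), with a call upward (camera adjusted p = 0.0133, and adjusted p = 0.389 with an estimated correlation). Cdx1 rose (0.69 ± 0.079). The list's call ended without low-level genes (0.0686). The DNA methylation enzymes were called higher (camera adjusted p = 0.00522, and adjusted p = 0.247 with an estimated correlation) on 2 genes of 9 measured, Dnmt3l and Tet2 (0.88 ± 0.055). Formative and primed markers were called higher (camera adjusted p = 0.044, and adjusted p = 0.674 with an estimated correlation) although of 18 measured members 5 rose and 2 fell (5 and 2 adjusted over the list alone), and Otx2 was among the falls. That call ended without low-level genes (0.0705), with fry (0.0594), and without DMSO replicate 1 (0.0596), DMSO replicate 2 (0.0706) or released replicate 3 (0.145). Krt18, which also stands in the trophectoderm list, was the largest of the 5 rises (1.59). The list's mean was 0.0985 and its median 0.0869, and the call was not tested without Krt18.

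Other lists were called on small shifts between released and DMSO arrays. Aminoacyl-tRNA synthetases had a median of 0.085 and were called higher (camera adjusted p = 0.00522, and adjusted p = 0.674 with an estimated correlation), although of 19 measured members 0 rose and 0 fell (4 and 0 adjusted over the list alone). There were 7 higher and 0 lower at an unadjusted limma p under 0.05. DNA replication had a median of 0.082 and was called higher (camera adjusted p = 0.0457, and adjusted p = 0.76 with an estimated correlation), although of 34 measured members 0 rose and 0 fell (0 and 0 adjusted over the list alone). There were 8 higher and 2 lower at an unadjusted limma p under 0.05. The DNA replication call held under 3 of 17 alternatives and ended when any array but DMSO replicate 2 was left out (adjusted p from 0.0509 to 0.107). In G2 and mitosis, of 29 measured members 1 rose and 0 fell (1 and 0 adjusted over the list alone), with a median of 0.09 and a call upward (camera adjusted p = 0.0106, and adjusted p = 0.674 with an estimated correlation). In oxidative phosphorylation, of 31 measured members 0 rose and 1 fell (0 and 1 adjusted over the list alone), with a median of -0.085 and a call downward (camera adjusted p = 0.0154, and adjusted p = 0.877 with an estimated correlation) that ended without DMSO replicate 2 (0.0706). In the heat shock and unfolded protein response, of 20 measured members 0 rose and 1 fell (0 and 4 adjusted over the list alone), with a median of -0.087 and a call downward (camera adjusted p = 0.0131, and adjusted p = 0.674 with an estimated correlation). In the xenobiotic and oxidative stress list, of 21 measured members 1 rose and 4 fell (1 and 7 adjusted over the list alone), with a median of -0.079 and a call downward (camera adjusted p = 0.0396, and adjusted p = 0.674 with an estimated correlation). This call ended without DMSO replicate 1 (0.096), released replicate 1 (0.0803) or released replicate 3 (0.0744), and Gstm1 (-0.44 ± 0.072) and Cyp1a1 (-0.64 ± 0.11) fell. With fry, adjusted p was 0.0594 for aminoacyl-tRNA synthetases, 0.0608 for G2 and mitosis, 0.0651 for heat shock and 0.186 for oxidative phosphorylation.

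Ribosome biogenesis was not called between released and DMSO arrays, as of 46 measured members 0 rose and 1 fell (0 and 0 adjusted over the list alone), with camera adjusted p = 0.832. In the naive and general pluripotency list, of 30 measured members 6 rose and 2 fell (8 and 4 adjusted over the list alone), without a call (camera adjusted p = 0.257). There, Dppa2 (1.15 ± 0.062) rose and Lin28a (-0.77 ± 0.084) was still lower. Pou5f1 differed by 0.16 ± 0.065 (limma adjusted p = 0.179), Sox2 by 0.01 ± 0.066 (0.945) and Nanog by 0.10 ± 0.052 (0.29), none past the threshold. With a variance trend and robust fitting Pou5f1 (0.00979), Nanog (0.0456) and Mycn (0.034) passed. Myc was higher than in DMSO (0.54 ± 0.11; limma adjusted p = 0.0148), a call that ended without DMSO replicate 1 (0.058) or released replicate 1 (0.0513), whereas Mycn differed by -0.14 ± 0.056 (0.177) and Max by -0.05 ± 0.067 (0.694). None of the 5 marker lists of other cell types was called (camera adjusted p from 0.527 to 0.982). The MYC network, cytosolic ribosomal proteins, translation factors and nucleotide biosynthesis were not called (camera adjusted p from 0.257 to 0.82). Cell cycle inhibitors and p53 targets, the integrated stress response, lysosome and autophagy and germline genes were not called either (camera adjusted p from 0.527 to 0.713).

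The genes that differed from DMSO in both conditions numbered 1129. Of these, 375 were higher in both, 290 lower in both, 244 higher with the inhibitor and lower after release, and 220 the reverse. The 464 with opposite directions became 301 without DMSO replicate 1 and 298 without DMSO replicate 2. The 665 with the same direction became 441 without DMSO replicate 1, 416 without released replicate 1 and 407 without released replicate 2. Independent lists of these sizes would give 162.8, 162.7, 140.1 and 189 genes. Both comparisons share the 3 DMSO arrays. In 100 simulations of unchanged groups against those arrays, at most 0 genes passed in both in the same direction, which is chance without any effect and no reference for lists of real changes. The log2 changes in the 2 comparisons correlated with r = 0.1335 across genes, which are not independent replicates, and the simulated value was 0.4473. The signs were equal for 57.36% of genes, against a simulated 64.76%. Both simulated values come from the shared arrays without any effect. They are therefore no reference for data with real changes and do not show less agreement than by chance. The covariance was 0.01195 against a simulated 0.003486. With the DMSO arrays divided 1 and 2 between the comparisons in each of the 6 ways, chosen after the data were seen, the covariance was 0.006747 to 0.007968, r was 0.07029 to 0.08548 and the signs were equal for 50.61% to 52.95% of genes. From 199 to 403 genes then passed in the same direction, against 95.35 to 191.2 for independent lists, and 158 to 313 in opposite directions, against 98.09 to 192.4. A single DMSO array was there assumed to vary like the other groups, and both comparisons still shared 1 estimate of the spread.

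**Figure D3:**
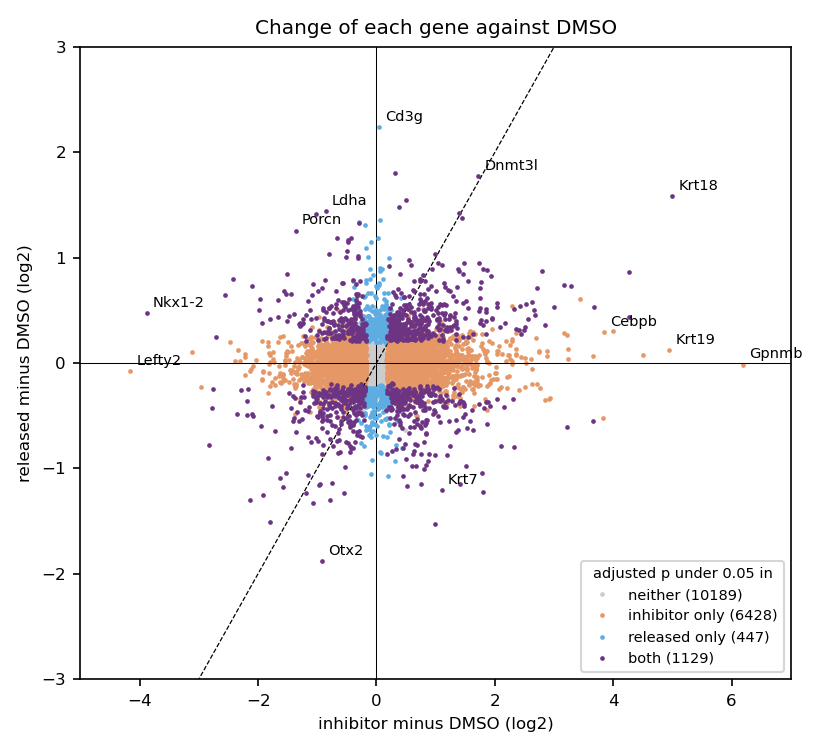
Log2 change of each of 18193 genes in inhibitor-treated against DMSO arrays (x axis) and in released against DMSO arrays (y axis). Colours show the comparison in which a gene passed an adjusted p of 0.05 (numbers in brackets), and the dashed line marks equal change; Gpnmb, Krt19 and Lefty2 lie far from 0 on the x axis and near 0 on the y axis, Krt18 is high on both, and Ldha is low on the x axis and high on the y axis.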

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

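Tests of mixed cells, of the 18S probe sets and with divided DMSO arrays were chosen only after the results they measure were seen. In opposite directions against DMSO, 464 genes passed the threshold in inhibitor-treated and in released cells. Among them were Ldha (-0.86 ± 0.062 and then 1.44 ± 0.056) and, chosen after their values were seen, Porcn (-1.36 ± 0.12 and then 1.26 ± 0.10) and Krt7 (1.10 ± 0.20 and then -1.21 ± 0.18). The count was 301 without DMSO replicate 1, 298 without DMSO replicate 2, 808 with a variance trend and robust fitting, and 158 to 313 with the DMSO arrays divided between the comparisons. Of the probe sets not named here, 1166 were higher and 634 lower in inhibitor-treated than in DMSO arrays, and 410 were higher and 63 lower in released than in DMSO arrays. In shares, 12.7% and 6.92% of them were higher and lower with the inhibitor, against 9.82% and 11.5% of named probe sets matched on level. After release the shares were 4.48% and 0.688%, against 1.87% and 1.41%.

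The simple keratins were higher in inhibitor-treated cells, with a median log2 change of 4.09 over 4 genes. Fibroblast or feeder cells in these samples would raise their own markers, but the median over 15 of these was -0.0745. After median centring the keratin median was 4.04. Centring shifted all changes by only -0.0476 on these already normalized values, so it could not test scaling as the source. Trophectoderm cells bringing their whole marker set are argued against by the median of 0.129 over the 12 trophectoderm markers that are not keratins, of which 4 rose and 2 fell. The 12 leave out Eomes, which stands here in the mesoderm list and rose by 2.23. A median over the set cannot tell whether only a part of it rose, or whether it rose in a few cells, and both stay open. No biological explanation was tested, and the source of the rise stays open.

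The glycolysis list was called higher in released than in DMSO cells (camera adjusted p = 0.00101), a call that did not hold with an estimated correlation (adjusted p = 0.389). A single array as the source is argued against, since the lowest median of the list with any of the 6 arrays left out was 0.315. Low oxygen or a denser culture in the released wells cannot be told apart from release. Of 26 known low-oxygen genes outside the list, written down before their values were seen, 5 rose (19.2%) and 1 fell. This lay between the bounds set for either answer, while of all 18193 genes 847 rose and 729 fell. The median of the 26 was 0.118, with camera p = 0.00201 and p = 0.222 with an estimated correlation. Bnip3 (1.38 ± 0.072) and Ankrd37 (0.71 ± 0.10) rose too. These are known low-oxygen genes not among the 26 and were chosen here after their values were seen. The 5 of the 26 that rose had these log2 changes with the inhibitor against DMSO: Anxa2 2.795, Vegfa 2.423, Ak4 0.646, P4ha1 0.44 and Fam162a -0.068. Whether their rise after release was a rest of that change was not tested. The 48 h of longer culture stays open too, untested.

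The 3 control probe sets for 18S ribosomal RNA were lower with the inhibitor by a mean log2 value of -1.63 (limma adjusted p from 8.03e-05 to 0.000529), outside the genes compared. Mean 18S values were 11.62, 11.14 and 11.52 on DMSO arrays, 9.68 and 9.91 on inhibitor-treated arrays, and 10.85, 10.59 and 10.11 on released arrays. Weaker hybridisation or labelling of all RNA as the whole cause is argued against by 42 of the 45 bacterial spike-in probe sets. These lay from 4.7 to 13.5 in DMSO, far enough above the Trpn sets to fall as much, and their median was -0.203 (from -0.697 to 0.0326). Added controls do not track how much 18S RNA entered the labelling, which was not measured. Expression of the ribosome biogenesis list at the time of sampling is argued against as the whole cause. After release the list's median against DMSO was 0.0297 while 18S still differed from DMSO by -0.908. A lasting effect of the list's earlier fall cannot be told apart by this test and stays open. On release 34 of the list's 46 measured members rose and 1 fell (camera adjusted p = 2.9e-08, and adjusted p = 0.202 with an estimated correlation). 18S then moved part of the way back, with a mean log2 value of 0.723 (limma adjusted p = 0.00729, 0.0109 and 0.117 for the 3 probe sets). A part that follows the list therefore stays open, as does what else lowered the 18S signal. Whether this signal tracks the amount of 18S RNA in the cells was not tested.

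The 6 DMSO and released arrays allow 10 splits into 3 and 3, too few for a share under 0.05. In 1 split, the real one, limma gave 1576 genes, against 0 in the highest of the others. For lists called, the real split gave 11 and the highest other 2. For genes changed the same way in both comparisons against DMSO, the real split gave 665 and the highest other 0. The last value follows from the 0 genes that passed in those splits and is no separate result.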

How the results depend on the processing

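Dividing the DMSO arrays between the comparisons was the 1 alternative chosen after the data were seen, and no call of a named gene or list changed direction in any of the others. For single lists, leaving out an array kept 675 verdicts, gained 5 calls and lost 16, and the other alternatives kept 690, gained 39 and lost 51. With every probe set tested, 13040 probe sets passed between inhibitor-treated and DMSO arrays, 12872 between released and inhibitor-treated arrays, and 1031 changed the same way in both comparisons against DMSO. With a variance trend and robust fitting, 2641 genes passed between released and DMSO arrays and 1168 changed the same way in both. With a 2-fold minimum, 880, 55 and 960 genes passed for inhibitor-treated against DMSO, released against DMSO and released against inhibitor-treated arrays, and at an adjusted p under 0.01, 657 passed for released against DMSO. With median centring 4978 genes were higher and 3237 lower in released against inhibitor-treated arrays. The causes of the shifts by the variance model and by centring were not tested. Camera with an estimated correlation called 0, 0 and 0 lists, and fry 27, 6 and 25.

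Leaving out 1 array gave 5931 to 7446, 1000 to 1344 and 6003 to 7637 genes, and 12 to 13, 8 to 10 and 11 to 13 lists, in the same order, and 407 to 508 genes changed the same way in both. The lowest counts for released against DMSO came without released replicates 1 (1008) and 2 (1000). With DMSO replicate 1, 2 or 3 alone for the inhibitor and the others for release, 359, 403 and 403 genes changed the same way, and with it alone for release 199, 279 and 209, where fewer arrays stood behind each comparison. Where 1 inhibitor-treated array remained, it was assumed to vary like the other groups. The replicate number as a block gave 6826, 1180 and 6825 genes, 12, 10 and 11 lists and 469 genes changed the same way. With it Esrrb (limma adjusted p = 0.067, from 0.000923 to 0.999 over its alternatives) and the aminoacyl-tRNA synthetases (camera adjusted p = 0.0661) did not pass with the inhibitor, nor DNA replication after release (0.0737), and no other call of a named gene or list was lost. Deviations of arrays with the same number correlated between -0.056 and 0.014, and not every array correlated best with its own number, so the numbers were not taken as pairs. Low signal limits genes near the bacterial control level, whose changes are compressed.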

Other observations

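No test in this part was chosen after its result was seen. Further lists were not called in inhibitor-treated against DMSO cells. In sterol biosynthesis, of 19 measured members 8 rose and 6 fell (8 and 6 adjusted over the list alone), without a call (camera adjusted p = 0.27). The regulator gene Srebf2 (0.77 ± 0.061) and the pathway genes Cyp51 (0.70 ± 0.069) and Hmgcs1 (0.62 ± 0.064) rose. In the heat shock and unfolded protein response, of 20 measured members 7 rose and 6 fell (8 and 6 adjusted over the list alone), with camera adjusted p = 0.34. Dnajc3, an endoplasmic reticulum co-chaperone gene, rose 2.5-fold, and the inducible Hspa1b fell (-1.61 ± 0.099). In the interferon response, of 18 measured members 1 rose and 5 fell (1 and 5 adjusted over the list alone), with camera adjusted p = 0.151. Oas1a (-1.53 ± 0.067) and the RNA sensor gene Ddx58 (-0.82 ± 0.065) fell.

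Among the DNA methylation enzymes, of 9 measured members 2 rose and 3 fell (2 and 3 adjusted over the list alone) with the inhibitor, with a median of -0.00436 and a mean of 0.0272, opposite in sign, and no call (camera adjusted p = 0.882). Dnmt3l rose (1.72 ± 0.089), and Uhrf1, which guides maintenance methylation, fell (-1.19 ± 0.068). Among markers of the 2-cell-like state, of 8 measured members 0 rose and 0 fell (0 and 0 adjusted over the list alone), without a call (camera adjusted p = 0.679). There were 0 higher and 1 lower at an unadjusted limma p under 0.05. In released against DMSO cells, sterol biosynthesis (camera adjusted p = 0.527), the interferon response (camera adjusted p = 0.649) and the 2-cell-like state (camera adjusted p = 0.717) were not called.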
